A study of Caenorhabditis elegans with 2 samples.

How the data were processed

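Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans L4 larvae in which the egl-43 gene on chromosome II carried a TY1, EGFP and 3xFLAG tag inserted by CRISPR. The antibody recognised GFP, and chromatin was fragmented by sonication, per the labels. The worms had been synchronised by starvation after bleaching and were collected at 49 hours. There were 2 samples, which the labels give as biological replicates 1 and 2 of 1 group. No second group, untagged worms or control library was analysed here, so every comparison is between sites and a genomic background, or between replicates.

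The deposited data are peak lists on the ce11 assembly, per the file headers and labels. Each replicate has a ranked list and a thresholded list, and the series has a ranked and a thresholded list for both replicates together, with a conservative version of each. The aligner and the peak caller are not given in the sources used here. The score of each peak is the irreproducible discovery rate (IDR) score that the authors deposited, in which a higher score stands for a more reproducible peak. The lowest score in each thresholded list was 830. The signal value of each peak is the authors' own. It was used to describe, rank, filter and compare peaks within a list, and to correlate paired peaks between the replicate lists. The −log10 q value that the authors deposited for each peak was not used. The authors also deposited the global IDR of each ranked peak on a logarithmic scale, and the highest global IDR in the series thresholded list was 0.0100. The summit offset in base pairs was deposited by the authors with each peak. Read depth is unknown, since the peak lists hold no counts, so the precision of a single signal value cannot be given. Wilson intervals on shares of summits cover counting error only. The thresholded lists leave out a few ranked peaks that pass the same score, 47 for the series, 55 for the conservative list, 37 for replicate 1 and 34 for replicate 2. The source of that exclusion is not given in the sources used here.

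The reference was the WBcel235 assembly with Ensembl release 115 annotation, which holds 19973 protein-coding genes and 29314 protein-coding transcription start sites (TSSs). The chromosome names matched the lists and every peak lay within its chromosome. The main list was the series thresholded list of 3146 peaks. A promoter ran from 1000 bp upstream to 500 bp downstream of a protein-coding TSS. Each summit was given the first class it met, with promoter first, followed by 5' UTR, coding exon, 3' UTR, intron, noncoding RNA gene and intergenic. Shares of summits were compared with 1000 random placements within chromosomes, with two-sided permutation p-values for which 0.0020 is the smallest they can give. Replicate overlap required 1 bp and was compared with 1000 random placements made with bedtools 2.31.1, with a one-sided permutation p for which 0.0010 is the smallest it can give. Signal values were set against each other by Pearson and Spearman correlation across peaks, without p-values because peaks are not replicates. The signal of promoter peaks was compared with that of the rest by a permutation test with 100000 resamples. Medians carry bootstrap intervals from 2000 resamples over peaks and correlations from 200. Overlap with a ranked list was compared with 100 placements.

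Genes with a promoter summit were counted in 22 gene lists by Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists. The tagged gene was left out of every list, and genes that share a name were counted singly. Genes on the X chromosome were compared with autosomal genes, and autosomal genes in the central 50% of the chromosome with those nearer the ends, by the same test. No paired analysis was possible because there is only 1 group. The lists, the comparisons, the 9 motifs and the following alternatives were chosen before the data were examined. They were the conservative list, peaks at or above the median signal, each replicate list in place of the other, narrower and wider promoters, other overlap criteria, other control windows, placement within 10 kb, other gene backgrounds and random lists matched on the number of TSSs and upstream length.

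Motifs were sought on either strand within 50 bp of the summit, and in windows of the same length centred 300 bp to either side. The test fixed beforehand was a sign test over peaks of the summit against the mean of both flanks. It was replaced after its results on the peaks had been seen. A motif found at similar rates everywhere is hit more often in 1 of 2 flanks than at the summit, so that test leans towards fewer hits at summits. The replacement is an exact test that, given the number of hits among the 3 windows of each peak, asks how often the summit window is among them. Both tests were run on simulated data only after this change. With random genome windows and nothing implanted, the sign test called 98.0% of 2080 6-mers and the exact test called none. In 40 simulated runs of 3000 windows without an implanted motif, the exact test called GATGAG in 7.5% of runs and the sign test in all of them. With the exact test and the motif implanted in 2% and 5% of windows, it was called in 95% and in all runs. The simulated summits and flanks were both random genome sequence, without the difference in GC content seen at the peaks. The simulations therefore cannot show how often the exact test calls a motif through GC content alone. On the peaks, the sign test called 8 of the 9 fixed motifs, 373 6-mers as more frequent and 1203 as less frequent, against 6, 1005 and 625 with the exact test.

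The gene list test was also tested on simulated data, with 8% of genes drawn at random. In 100 runs it called 0.0455% of unchanged lists, and a list of 76 genes drawn with a fold of 3 was called in 88% of runs and with a fold of 5 in all. The promoter share test called 8.33% of 60 random sets of 1500 summits, and 76.7% of sets in which 5% of the summits had been moved to TSSs. Further alternatives were chosen after seeing the data. These are random lists matched on the number of TSSs and the highest GC content in the promoter window, the removal of peaks with a signal under 50, 6-mers against controls matched on GC content within 3 percentage points and on distance to the TSS, and the sign test kept as an alternative. A scan of gene families with at least 20 members was also chosen after seeing the data. Of the 79 peaks with a signal under 50, 77 overlapped a stronger ranked peak.

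Named genes followed a fixed rule. It takes egl-43, the genes nearest the 12 strongest promoter peaks, and up to 3 members with the strongest promoter summit in each list past the threshold and in the anchor cell, Notch, Wnt, axon guidance and heterochronic lists. It also takes the anchor cell genes without a summit from 5 kb upstream to the gene end, and the 3 strongest intergenic peaks over 5 kb from a protein-coding TSS. Genes named outside this rule are said to be chosen after their values were seen. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.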

Results

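EGL-43 is a zinc finger transcription factor related to mammalian EVI1, with known roles in anchor cell invasion and in neuronal migration. ChIP-seq peaks of the GFP-tagged protein in whole L4 larvae, in 2 biological replicates of 1 group, are called sites below. No untagged worms were used here, so binding of EGL-43 cannot be told apart from background at any group of sites. The series list held 3146 peaks with a median width of 330 bp, covering 960321 bp. The replicate 1 list held 1532 peaks and the replicate 2 list 1621. The signal value quoted for a peak is the authors' own, and levels are compared only within a list, apart from the correlation between replicates. The number of reads per library is unknown.

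The first question was whether both replicates gave the same sites. Of the replicate 1 peaks, 64.8% overlapped a replicate 2 peak, against a mean of 0.931% for randomly placed peaks. Of the replicate 2 peaks, 61.1% overlapped a replicate 1 peak, against 0.893%. The permutation p was 0.0010 in both directions, the smallest that 1000 placements can give. Among the 500 strongest peaks of each replicate the share was 78.2%. Set against the much longer ranked list of the other replicate, 93.7% of replicate 1 peaks and 97.8% of replicate 2 peaks had a counterpart, against 32.9% and 35.6% for random placements. In the series list, which most results below use, 42.5% of peaks overlapped a replicate 1 thresholded peak. The share that overlapped a replicate 2 thresholded peak was 47.1%. Across 45991 pairs of peaks in the ranked lists, the signal values had a Spearman correlation of 0.486 (95% bootstrap interval 0.477 to 0.492) and a Pearson correlation of 0.477 on the log2 scale. Across the 961 pairs in the thresholded lists, which hold the more reproducible peaks by selection, these were 0.812 (0.783 to 0.833) and 0.827.

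**Figure D1:**
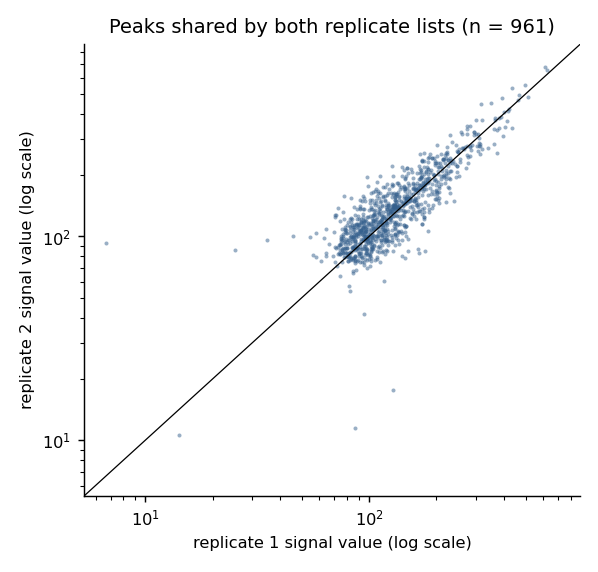
Signal values of the 961 peaks shared by both replicate lists, with replicate 1 on the x axis and replicate 2 on the y axis, both on log scales. Each point is 1 peak, the line of equal values is a guide to the eye, as levels are not compared between lists, and the Spearman correlation across these peaks is 0.812.

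The next question was where in the genome the sites lie. Promoters of protein-coding genes held 44.5% of summits, 1399 of 3146 (95% Wilson interval 42.7 to 46.2), against 31.3% for random placements. The share was 45.2% in each replicate list. Noncoding RNA genes outside both promoters and protein-coding genes held 5.94%, against 0.775% at random. By the order of classes, summits at noncoding RNA genes within introns of protein-coding genes count as intron. Introns held 18.5%, intergenic DNA 16.9% and coding exons 12.8%, each below the random shares of 24.95%, 23.9% and 16.5%. Each of these classes had a permutation p of 0.0020, the smallest the placements can give. The 3' UTRs held 1.08%, against 2.30%, at the same p, and the 5' UTRs held 0.254%, against 0.245%, at a permutation p of 1.0. Coding exons held 6.20% of summits in the replicate 1 list and 7.71% in the replicate 2 list, under 12.8% in the series list.

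Summits lay on both sides of the nearest TSS, 52.6% of them upstream, and 16.1% were within 200 bp of it. The median of the signed distances was -56 bp (95% bootstrap interval -94 to -25.5). In the stronger peaks, those at or above the median signal, it was -176 bp. There were 195 summits over 5 kb from a TSS. Promoter peaks had a slightly higher signal than the rest, by 0.05 on the log2 scale with a permutation p of 0.0127. That difference turned to -0.02 among the stronger peaks, with a permutation p of 0.583, and to -0.04 in the replicate 1 list, with a permutation p of 0.284. In the replicate 2 list it was 0.04, with a permutation p of 0.125. Coding exon peaks had a median signal of 122 (bootstrap interval 121 to 124), against 142 (139 to 145) for promoter peaks. The median was 143 (138 to 148) for intergenic peaks and 143 (138 to 151) for intron peaks. For peaks in noncoding RNA genes outside promoters and protein-coding genes it was 191 (175 to 203). Promoter peaks were thus not stronger than the intergenic, intron and noncoding RNA gene classes.

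**Figure D2:**
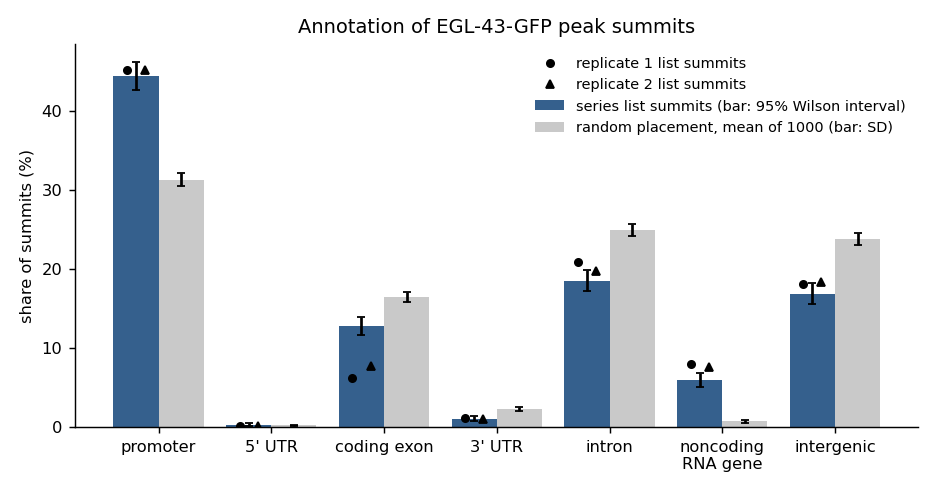
Share of summits in each annotation class, in percent, for the series list (blue bars, 95% Wilson intervals), the mean of 1000 random placements (grey bars, SD) and each replicate list (points). Promoters held 44.5% of summits against 31.3% at random, and coding exons fewer in each replicate list than in the series list.

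Small RNA genes were prominent among the sites. Summits lay within 500 bp of a tRNA gene in 10.2% of cases, 320 of 3146, against 0.596% at random. For snoRNA genes the share was 3.15%, against 0.384%, and for snRNA genes 1.08%, against 0.125%. The adjusted permutation p was 0.00266 for each of these, from the smallest p the placements can give. In the shorter replicate lists the shares were higher, at 21.3% and 18.1% for tRNA genes and 5.16% and 5.06% for snoRNA genes. The numbers of summits were not higher to that extent, with 326 and 294 for tRNA genes, against 320 in the series list. For snoRNA genes they were 79 and 82, against 99. Against placements within 10 kb of each peak, the random shares were 1.46% for tRNA genes and 0.783% for snoRNA genes, so the ratio to random fell from 17.1 to 6.98 and from 8.20 to 4.02. No summit of the thresholded list lay near an rRNA gene, which allows a share of up to 0.122% (Wilson), against 0.0229% at random. Of the 47 peaks past the same score that this list leaves out, 4 lay within 200 bp of rRNA genes, so the absence rests on that exclusion. Counted by gene, 344 of 612 tRNA genes (56.2%) had a summit within 200 bp, with 58.3% in the replicate 1 list and 52.5% in the replicate 2 list. On the X chromosome, which holds 276 of the tRNA genes, the share was 55.4%, and on the autosomes it was 56.8%. Of snoRNA genes 22.5% had a summit within 200 bp, 78 of 346, and of snRNA genes 25.6%, which is 33 genes.

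Peaks at small RNA genes were also strong ones. The median signal was 247 (bootstrap interval 230 to 266) within 200 bp of a tRNA gene and 299 (222 to 362) within 200 bp of a snoRNA gene, against 135 (133 to 136) for the other peaks. Of the 50 strongest peaks, 30% had a snoRNA gene within 200 bp and 16% a tRNA gene. Of the peaks ranked after the 100 strongest and up to 200, 44% had a tRNA gene within 200 bp, and of those ranked 2001 to 3146, 1.22%. The following peaks were chosen after their values were seen. The strongest, with a signal of 1279, lay at V 12303443 to 12303795, in an intron of frm-7 next to 2 snoRNA genes. The next, with a signal of 1270.0, lay in an intron of pxn-1 at V 8500403 to 8500705, next to the snoRNA gene ZK994.7. The peak of rank 4, with a signal of 1001.4, lay at I 13463803 to 13464166 in an intron of ints-8 that contains rpr-1, the RNA of ribonuclease P.

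**Figure D3:**
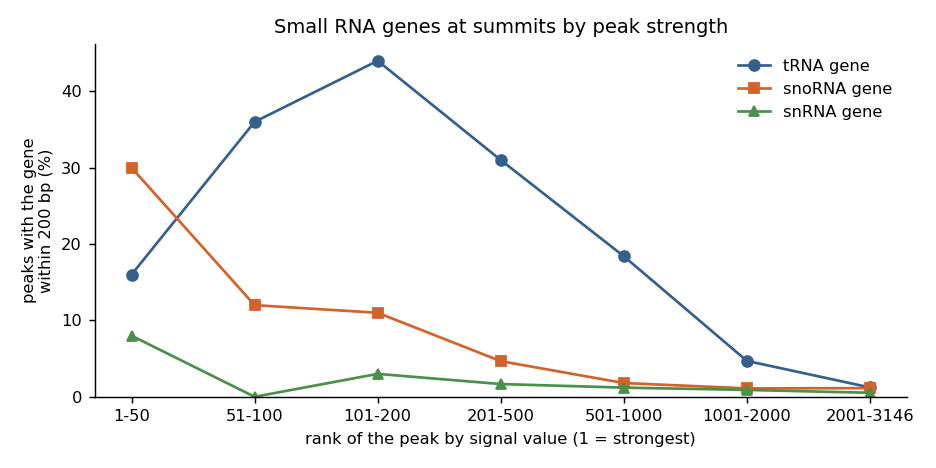
Percent of peaks with a tRNA, snoRNA or snRNA gene within 200 bp (y axis) by rank of signal value (x axis, rank 1 strongest) in the series list. The snoRNA share was 30% in the 50 strongest peaks, and the tRNA share reached 44% in the bin that ends at rank 200.

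The strongest promoter peak belonged to rpl-3, which encodes a protein of the large ribosomal subunit. It lay at III 3867432 to 3867710 with a signal of 1041, its summit 283 bp upstream of the TSS, and had signals of 499 and 554 in replicates 1 and 2. The promoter of tasp-1, the relative of the protease taspase, followed with 936 at III 10759112 to 10759394. The promoter of F44E5.4, a member of the HSP70 chaperone family, had 803 at II 11759308 to 11759657. The other 9 of the 12 strongest promoter peaks were nearest to K08F11.1 (signal 770), sre-23 (726), nspc-17 (710), Y75B12B.11 (679), mtcu-2 (646), twk-5 (626), F55A11.6 (624), egg-5 (620) and C28G1.2 (619). Several of these promoters also hold a small RNA gene within 200 bp of the summit. These are snoRNA genes at sre-23, Y75B12B.11, twk-5 and F55A11.6, an SL2 spliced leader gene at egg-5 and a tRNA gene at C28G1.2. The strongest intergenic peaks far from a TSS lay at I 2514186 to 2514491 (signal 772, beside the snoRNA gene Y23H5B.10), X 13700725 to 13701028 (581) and I 10462579 to 10462908 (444).

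A promoter summit was found at 1511 of 19973 protein-coding genes (7.57%). The replicate 1 list gave 787 genes, the replicate 2 list 821, and 537 genes were in both. Of the 22 gene lists, 5 passed the test against the other genes. Ribosomal protein genes carried a promoter summit most often, 31 of 76 (40.8%), with an odds ratio of 8.57 (exact 95% interval 5.23 to 13.9) and an adjusted p of 9.68e-15. After rpl-3, the strongest were rpl-35 with a signal of 585 and rpl-15 with 561. Chemoreceptor genes, a large family expressed mainly in sensory neurons, carried one least often among these 5 lists, 18 of 1308 (1.38%), with an odds ratio of 0.160 (0.0945 to 0.256) and an adjusted p of 3.41e-24. Both calls held in each replicate list and against random lists matched on TSS number and promoter GC, where the ratio of observed to expected genes moved from 5.39 to 2.85 for ribosomal protein genes and from 0.182 to 0.410 for chemoreceptor genes. The strongest of these 18 were at sre-23 (signal 726, beside a snoRNA gene), srh-269 (433, beside a tRNA gene) and srz-97 (201, beside a snRNA gene).

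Histone genes carried a promoter summit in 12 of 72 cases (16.7%), with an odds ratio of 2.46 (1.199 to 4.62) and an adjusted p of 0.0478, close to the threshold. The strongest was at his-37, with a signal of 385, followed by a summit shared by his-59 and his-60, with 198. The 12 genes rest on 8 distinct summits, since 8 of them share theirs in pairs, and the test counts them as separate genes. The call ended with gene bodies and 5 kb upstream (1.41, adjusted p 0.418) and with only the nearest TSS counted (2.14, adjusted p 0.150). It also ended against random lists matched on TSS number and promoter GC, chosen after the data were seen, with a ratio of observed to expected genes of 1.21 and an adjusted permutation p of 1.0.

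C-type lectin genes carried a promoter summit in 8 of 240 cases (3.33%), with an odds ratio of 0.418 (0.178 to 0.840) and an adjusted p of 0.0478, as close to the threshold. The strongest were at clec-126 (signal 305, beside 2 tRNA genes), at clec-57, which shares its summit with srz-97, and at clec-91 (119.6). The call ended in the conservative list (0.439, adjusted p 0.0723), in the replicate 2 list (0.293, adjusted p 0.0900) and with only the nearest TSS counted (0.511, adjusted p 0.165). It also ended against random lists matched on TSSs and upstream length (0.513, adjusted p 0.169) or on TSS number and promoter GC (0.484, adjusted p 0.176). The Benjamini-Hochberg adjustment carried the value of 0.0478 over from the histone genes, so the lectin call depends on the histone call.

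Among 16 heterochronic genes, which time events of larval development, 6 carried a promoter summit (37.5%), with an odds ratio of 7.35 (2.19 to 22.4) and an adjusted p of 0.00562. The strongest were at lin-66 (signal 246), lin-28 (218), which encodes an RNA-binding protein, and dre-1 (149), which encodes an F-box protein. The lin-28 peak had a signal of 106 in replicate 1 and no matched signal in replicate 2. This call rested on few genes. It ended in the replicate 1 list (3 genes, odds ratio 5.64, adjusted p 0.102), in the replicate 2 list (1 gene, 1.56, adjusted p 0.794), among the stronger peaks (3 genes, 5.14, adjusted p 0.129) and against genes with a ranked peak in the promoter (3.37, adjusted p 0.107). Against random lists matched on TSSs and upstream length the ratio of observed to expected genes was 3.00 (adjusted p 0.0913), and on TSS number and promoter GC it was 1.87 (adjusted p 0.508).

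**Figure D4:**
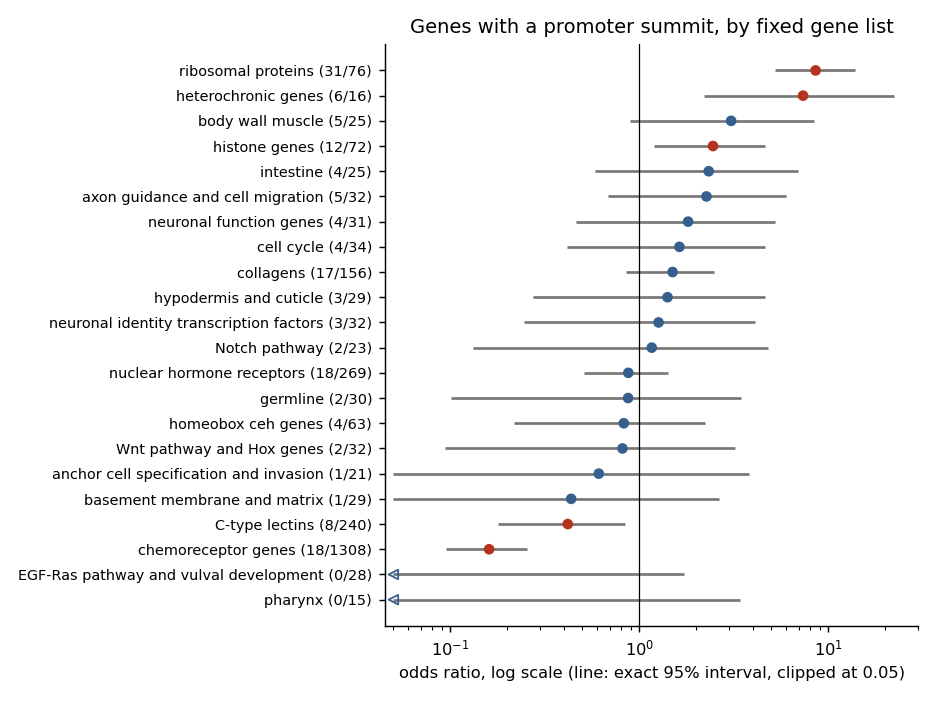
Odds ratio of carrying a promoter summit for each of the 22 gene lists (x axis, log scale, exact 95% intervals as lines), with the genes that carry one and the list size in brackets. Red points have an adjusted p under 0.05, open triangles mark lists with no such gene, and ribosomal protein genes (8.57) have the highest odds ratio and chemoreceptor genes (0.160) the lowest above 0.

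The other 17 lists did not pass the threshold. Body wall muscle genes came nearest, with 5 of 25 and an odds ratio of 3.06 at an adjusted p of 0.134, and passed with narrower promoters (5.09, adjusted p 0.0235). Against random lists matched on TSS number and promoter GC, 4.79 genes were expected, a ratio of observed to expected genes of 1.04. The odds ratio differed between replicates, with 1 of 25 in the replicate 1 list (1.02, adjusted p 1.0) and 4 of 25 in the replicate 2 list (4.46, adjusted p 0.0900). Cell cycle genes passed with promoters that reach 2000 bp upstream (9 of 34, 3.11, adjusted p 0.0291). With gene bodies and 5 kb upstream, neuronal function genes (15 of 31, 3.98, adjusted p 0.000775) and collagens (56 of 156, 2.39, adjusted p 6.87e-06) passed. That window grows with gene length, for which the lists were not matched. The remaining counts were 17 of 156 collagens, 5 of 32 axon guidance genes, 4 of 25 intestinal genes, 4 of 31 neuronal function genes, 4 of 34 cell cycle genes, 3 of 29 hypodermal genes and 3 of 32 neuronal identity factors. They were 2 of 23 Notch genes, 2 of 32 Wnt and Hox genes, 2 of 30 germline genes, 4 of 63 ceh homeobox genes, 18 of 269 nuclear hormone receptors and 1 of 29 basement membrane genes. None of 28 EGF-Ras and vulval genes or of 15 pharyngeal genes had one, which at these list sizes leaves odds ratios up to 1.72 and 3.41 within the exact intervals. In the axon guidance list the strongest was at the fibroblast growth factor gene egl-17 (signal 537, beside a tRNA gene), then at the Eph receptor gene vab-1 (136) and at unc-76 (128.8). In the Notch list they were at dos-1 (400.0, beside a tRNA gene) and osm-11 (158), which encode secreted co-ligands. In the Wnt list they were at lit-1 (198), which encodes a Nemo-like kinase, and the Dishevelled gene mig-5 (164). Neither vab-1 nor osm-11 had a promoter summit in either replicate's thresholded list, and unc-76 had one only in that of replicate 2.

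Genes of anchor cell specification and invasion, the setting in which egl-43 is best known, did not stand out. A promoter summit was found at 1 of 21, with an odds ratio of 0.611 (0.0147 to 3.82) and an adjusted p of 1.0. That gene was fos-1, a bZIP factor gene required for invasion, with a signal of 113 and no promoter summit in either replicate's thresholded list. With the gene body and 5 kb upstream counted, 4 of 21 had a summit, namely fos-1, him-4, mig-10 and pat-3, the last 3 named after their values were seen. Of all protein-coding genes 19.1% had one. The 17 members without a summit there were nhr-67, hlh-2, lag-2, lin-12, lin-3, zmp-1, cdh-3, ina-1, unc-6, unc-40, unc-34, ced-10, mig-2, cki-1, hda-1, egl-13 and let-418. A peak in an intron of him-4, with a signal of 868 and rank 8, lay within 200 bp of tRNA genes. The anchor cell is a single cell of the whole animal, and the worms were not dissected.

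The tagged gene itself held 2 summits. The first, at II 9960006 to 9960335 with a signal of 147, lay 60 bp upstream of an internal TSS at 9960231, inside the gene at 9955185 to 9963020. Its signal was 82.7 in replicate 1 and 60.9 in replicate 2. The second, at II 9952710 to 9953039 with a signal of 147, was intergenic, 2310 bp upstream of the first TSS, with 70.3 and 68.9. They ranked 1374 and 1381 of 3146 peaks. The replicate 1 thresholded list held the first and not the second, and the replicate 2 thresholded list held neither. Of 1118 genes within 20% of its length, 174 (15.6%) also had at least 2 summits from 10 kb upstream to the gene end.

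Summits were spread unevenly over chromosomes, from 23.3 peaks per Mb on V to 39.2 on III, with 36.4 on I and 35.3 on X. This spread was not tested. The share of genes with a promoter summit ran from 5.27% on chromosome V to 10.04% on chromosome I, with 9.28% on III, 8.50% on X, 7.31% on II and 7.01% on IV. Genes on X carried one in 8.50% of cases and autosomal genes in 7.42%, with an odds ratio of 1.16 (0.997 to 1.34) and a p of 0.0514 by Fisher's exact test. The autosomal share includes the low chromosome V, and chromosomes I and III lay above X, so this comparison does not set X apart from each autosome. The test passed among the stronger peaks, with 1.27 and a p of 0.0129, in the replicate 1 list, with 1.298 and a p of 0.00939, in the replicate 2 list, with 1.302 and a p of 0.00692, and with promoters that reach 2000 bp upstream, with 1.15 and a p of 0.0336. Autosomal genes in chromosome centres carried one in 7.11% of cases and those in the outer parts in 7.81%, with an odds ratio of 0.903 and a p of 0.0844, which did not pass the test. It passed with promoters that reach 2000 bp upstream, with 0.895 and a p of 0.0277, and the direction turned among the stronger peaks (1.02), in the replicate 1 list (1.09) and with narrower promoters (1.03).

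Summits lay in GC-rich sequence. The mean GC content within 50 bp of summits was 52.5%, against 35.8% in windows 300 bp away and 35.4% in the genome. It was 52.4% in the replicate 1 list and 53.1% in the replicate 2 list. The GA repeat GAGAGA, a control chosen because it is seen at many accessible worm sites, lay within 50 bp of 16.4% of summits, against 6.52% of flanks (adjusted p 1.62e-49), and of 16.5% against 9.55% with controls matched on GC content and TSS distance (adjusted p 1.4e-15). The core GATGAG, fixed from knowledge of EVI1, lay at 6.45% of summits and in 4.18% of flanks (odds ratio 1.58, adjusted p 1.37e-05) by an exact test adopted after the first results had been seen. In the replicate 1 list it did not pass (1.24, adjusted p 0.180), and in the replicate 2 list it did (1.52, adjusted p 0.00519). By the sign test fixed beforehand the ratio was 0.846 with an adjusted p of 0.0871, but that test gives ratios under 1 where nothing differs, and the reversed controls GAGTAG and GTCCTT had 0.653 and 0.543. With GC-matched controls GATGAG lay at 6.46% of summits and in 7.33% of control windows (0.871, adjusted p 0.427). AAGATGA and GATAAGA were less frequent at summits than in flanks, with odds ratios of 0.595 and 0.481, and so were the reversed control sequences AGTAGAA (0.504) and AGAATAG (0.475). With GC-matched controls none of these 4 passed the test. Against flanks at 500 bp AAGATGA (0.710, adjusted p 0.0651) and AGTAGAA (0.691, adjusted p 0.140) did not pass, while GATAAGA and AGAATAG did. TTCCTG, a site of the ETS type, lay at 4.39% of summits and in 5.18% of flanks and did not pass (adjusted p 0.113). It passed as less frequent in the replicate 1 list (0.628, adjusted p 0.0181) and not in the replicate 2 list (0.840, adjusted p 0.322). With GC-matched controls TTCCTG was less frequent at summits (0.679, adjusted p 0.00227). The reversed controls GAGTAG (1.27, adjusted p 0.107) and GTCCTT (1.03, adjusted p 0.902) did not pass against flanks at 300 bp. GAGTAG passed as more frequent against flanks at 500 bp (1.51, adjusted p 0.0120, above the 1.25 of GATGAG there), within 100 bp of the summit (1.42, adjusted p 0.000627) and in the conservative list (1.40, adjusted p 0.0285). GTCCTT passed within 100 bp (1.24, adjusted p 0.0334), and it passed as less frequent with GC-matched controls (0.503, adjusted p 5.53e-06).

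Over all 2080 6-mers, the exact test called 1005 more frequent at summits, with a mean GC content of 65.9%, and 625 less frequent, with a mean of 26.6%. The lead ones were CGCCGC, at 13.1% of summits against 2.02% of flanks, and AAAAAT, at 13.4% against 46.7%. With controls matched on GC content and TSS distance, 214 and 196 were called. The lead one was then GTTCGA, part of the B box of tRNA promoters, at 9.97% against 4.18%, followed by ACGCAG, at 10.8% against 4.89%, and AGAGAG, at 14.4% against 7.72%.

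**Figure D5:**
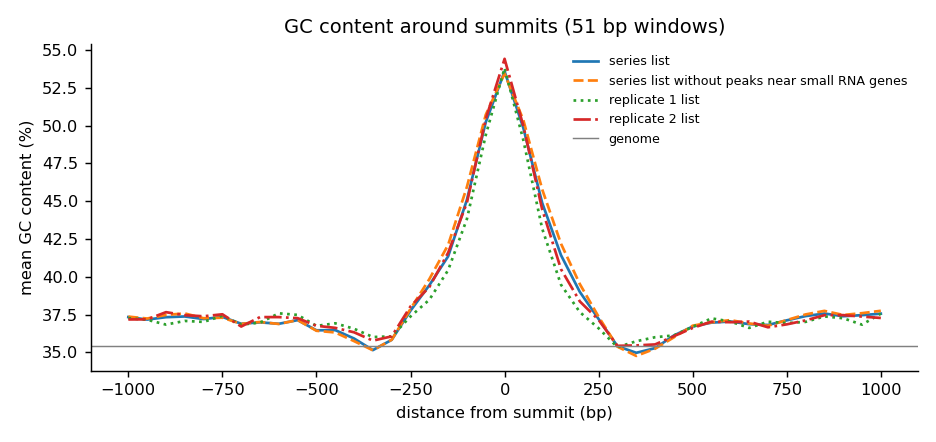
Mean GC content in percent (y axis) in 51 bp windows by distance from the summit in bp (x axis), for the series list, the series list without peaks near small RNA genes and each replicate list, with the genome mean as a grey line. The y axis does not start at 0, and all 4 lines peak at the summit and return to near the genome mean within 300 bp.

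The ranked series list held 62495 further peaks, most of them below the threshold and 47 of them past its score but left out of the thresholded list. Among the 3000 strongest of them, 35.3% of summits lay in promoters, against 44.5% in the thresholded list, and among those ranked after 48000, 30.7%. Ribosomal protein genes had a promoter summit in 27.6% of cases among those 3000 peaks and chemoreceptor genes in 0.917%, against 5.87% of all genes. The share of peaks within 200 bp of a tRNA gene was 0.667% among the 3000 strongest and 0.110% among those ranked after 48000.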

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

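The test of a GC bias of the library, that of small RNA genes as the source of the GC content and those of promoter GC were chosen only after the result was seen. The tests on tRNA and snoRNA genes were set before their values were computed. Since the samples form 1 group, no biological explanation was tested.

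A signal appeared outside the peaks that the comparisons use. The series thresholded list leaves out 47 ranked peaks that pass the same score. The strongest of them, at X 15810935 to 15811185, had a signal of 3470.2, which is 2.71 times that of the strongest peak kept. Its signals were 2028 and 1579 in replicates 1 and 2. Of the 47 peaks 37 were intergenic, none lay in a promoter and 7 lay within 500 bp of a small RNA gene. Joined over 20 kb they formed 23 groups, and 34 peaks lay in the 10 groups with 2 or more, such as 7 peaks at I 10946004 to 10951940 and 6 at V 17118789 to 17129608, of which 4 lay within 200 bp of rRNA genes.

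A summit of any signal lay within 200 bp of 56.2% of tRNA genes and 22.5% of snoRNA genes. Windows of the same GC content away from small RNA genes held a summit in 6.54% of cases for tRNA genes (Wilson interval 5.94 to 7.18) and 1.82% for snoRNA genes (1.43 to 2.32), which argues against GC content as the whole cause. Of 143 tRNA genes with no identical copy among the annotated tRNA genes, 42.7% had a summit (34.8 to 50.9), against 60.3% of 469 with identical copies. This argues against reads shared between identical copies as the whole cause, while a part in the difference between these shares stays open. Reads shared with nearly identical sequences were not tested and stay open as well. Open explanations include chromatin or antibody background at highly transcribed small RNA genes, for which untagged worms and other tagged factors were not used here.

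The GC-rich sequence at summits was set against a bias of the library. At equal GC content, promoter windows held summits 3.07 times as often as coding exon windows (95% interval 2.74 to 3.44), so GC content does not set the sites by itself. The same ratio was 1.37 (1.23 to 1.53) over introns and 1.46 (1.32 to 1.62) over intergenic windows, closer to even. The share of windows with a summit rose with GC content in each class, from 0.0113% under 30% GC to 13.2% over 60% in promoters and from 0.00616% to 7.71% in intergenic DNA, so a bias that adds to the pattern stays open. Without the 450 peaks near small RNA genes the mean GC content was 52.6% (52.3 to 52.9), against 52.5% over all peaks and 35.8% in flanks. This argues against those genes as the source of the high mean. The bound set for that test, 44.2%, lay out of reach of so few peaks, so the bound itself decides nothing.

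The gene list calls were set against random lists matched on TSS number and promoter GC together. Ribosomal protein genes had 2.85 times the expected number and chemoreceptor genes 0.410 times, both with an adjusted permutation p of 0.00220 from the smallest p that 10000 random lists can give, which argues against promoter GC as the whole cause, though the unmatched ratios were 5.39 and 0.182. Histone genes numbered 12, where 5.45 were expected unmatched (95% of random lists 2 to 10; ratio 2.203) and 9.96 matched (5 to 16; ratio 1.21). Their call ended because the expected number rose, and as it held when matched on TSSs and upstream length (ratio 2.52, adjusted permutation p 0.0323), promoter GC is a candidate explanation. Heterochronic genes numbered 6, where 1.21 were expected unmatched (0 to 4; ratio 4.96), 2.00 when matched on TSSs and upstream length, which already ended the call, and 3.22 (1 to 6; ratio 1.87) with TSS number and promoter GC, so for these 16 genes promoter GC cannot be told apart from TSS number or the gene group.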

How the results depend on the processing

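The tests against promoter GC, without peaks of signal under 50, with GC-matched 6-mer controls and with the sign test as an alternative were chosen only after the results were seen, and the others beforehand. Where the cause of a change is not given, the cause was not tested. Read depth is unknown, so its effect could not be followed.

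The share of promoter summits and those near tRNA, snoRNA and snRNA genes stayed above random under every alternative run on them. The calls on ribosomal protein and chemoreceptor genes held in 13 of 13 alternatives (adjusted p up to 0.00220), that on histone genes in 10 (up to 1.0), that on C-type lectins in 8 (up to 0.176) and that on heterochronic genes in 7 (up to 0.794). Over 22 gene lists and 286 alternative values, 227 kept direction and side of the threshold, 14 lost the call, 4 gained one and 41 changed direction, all of these called in neither setting. Of 72 motif values, 49 kept both, 6 lost the call, 7 gained one and 10 changed direction, 6 of these called in 1 of the settings. The sign test, which leans to lower values, gave 3 of the 10 and 3 of the 6. Of the lists, 5 were called, against 3 to 4 without 1 replicate, 3 with only the nearest TSS, 6 each with narrower promoters, with 2000 bp upstream and with gene bodies, 3 when matched on TSSs and upstream length and 2 when matched on TSS number and promoter GC.

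Without 1 replicate, which means fewer peaks, values ranged from 1532 to 1621 for the number of peaks, 787 to 821 for genes with a promoter summit, -165 to -128 bp for the distance to the TSS, 1.298 to 1.302 for the X chromosome, 0.909 to 1.09 for chromosome centres, -0.0432 to 0.0422 for the log2 signal of promoter peaks and 0 to 0.0653% for rRNA genes. Odds ratios ranged from 1.56 to 1.63 for Wnt genes, 1.02 to 4.46 for body wall muscle genes, 0 to 1.63 for neuronal identity factors, 0.972 to 2.12 for intestinal genes, 0.612 to 0.975 for collagens, 0.812 to 1.61 for neuronal function genes, 0 to 1.73 for hypodermal genes, 0 to 1.74 for germline genes, 0.376 to 0.392 for ceh genes, 0.203 to 0.293 for C-type lectins, 3.07 to 3.796 for histone genes, 0.553 to 0.712 for nuclear hormone receptors, 0 to 0.871 for basement membrane genes, 0 to 0.864 for EGF-Ras genes, 1.56 to 5.64 for heterochronic genes, 0.308 to 0.364 for AGTAGAA, 0.962 to 0.986 for GAGTAG and 0.975 to 1.46 for GTCCTT.

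Among peaks at or above the median signal, the TSS distance was -176 bp, 861 genes had a promoter summit, and the ratios were 1.27 for X, 1.02 for chromosome centres, 1.48 for Wnt genes, 0.716 for axon guidance genes and for neuronal identity factors, 0.793 for hypodermal genes and 0.733 for collagens, with a log2 signal difference of -0.0155. The replicate signal correlation was 0.495 with 50% reciprocal overlap and 0.812 in the thresholded lists. The conservative list gave 0.855 for neuronal identity factors and 0.9504 for hypodermal genes.

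Promoters of 500 bp upstream and 200 bp downstream gave 938 genes and ratios of 1.03 for chromosome centres, 1.01 for anchor cell genes, 0 for Notch genes, 1.35 for Wnt genes, 0.654 for neuronal identity factors, 0.724 for hypodermal genes, 1.01 for ceh genes and 0.396 for collagens. With 2000 bp upstream they were 1.15 for X, 0.895 for chromosome centres, 0.8200 for Notch genes, 1.23 for Wnt genes, 1.03 for EGF-Ras genes and 1.08 for ceh genes. Gene bodies and 5 kb upstream gave 0.892 for Notch genes, 1.11 for basement membrane genes and 1.33 for ceh genes. Against genes with a ranked peak, the ratios were 0.935 for Notch genes, 0.841 for hypodermal genes and 1.25 for nuclear hormone receptors. Notch genes had 0.6199 without peaks near small RNA genes. With only the nearest TSS, germline genes had 1.07 and nuclear hormone receptors 1.01. Matched on TSS number and promoter GC, the ratios were 0.844 for Notch genes, 0.636 for neuronal identity factors, 0.734 for hypodermal genes, 1.12 for nuclear hormone receptors and 0.696 for collagens.

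By the sign test the motif ratios were 0.846 for GATGAG, 0.653 for GAGTAG and 0.543 for GTCCTT, with 373 6-mers more frequent and 1203 less frequent, and the construction of that test leans to lower values. With flanks at 500 bp GTCCTT had 0.919. With GC-matched controls 3 of the 9 motifs were called, GATGAG had 0.871, AGTAGAA 1.12 and GTCCTT 0.503, and 214 and 196 6-mers were called.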

Other observations

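The scan of gene families reported here was chosen only after the results on the fixed lists were seen. Among 94 families with at least 20 protein-coding members sharing a name, 19 differed from the other genes in Fisher's exact test, 11 with more promoter summits and 8 with fewer. Beyond the ribosomal rpl and rps families, promoter summits were frequent among the lin genes (15 of 47, odds ratio 5.77, adjusted p 2.47e-05), a group named for lineage mutants, and the unc genes (20 of 94, 3.33, adjusted p 0.000373), named for uncoordinated movement, of which 5 had one in the replicate 1 list and 14 in the replicate 2 list. The lin group shares members with the heterochronic list, such as lin-28 and lin-66, so the 2 results are not separate. Subunits of the vacuolar proton pump, the vha genes, carried one in 7 of 20 cases (6.60, adjusted p 0.00604). The vps genes of vacuolar sorting had 8 of 31 (4.27, adjusted p 0.0188) and the eif genes of translation initiation 7 of 25 (4.77, adjusted p 0.0188), with 2 and 6 in the replicate lists. The chaperone families had 6 of 22 for hsp (4.596, adjusted p 0.0311) and 7 of 29 for dnj (3.90, adjusted p 0.0311).

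Fewer promoter summits were found in the chemoreceptor families str (0 of 193, adjusted p 1.14e-05) and srw (0 of 109, adjusted p 0.00567) and in the F-box family fbxa (3 of 170, adjusted p 0.0188). This did not extend to every chemoreceptor family, since 6 of 61 sri genes carried one (odds ratio 1.33, adjusted p 0.623).

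Against random families matched on TSS number and promoter GC, the ratio of observed to expected genes went from 5.06 to 2.67 for rpl (adjusted permutation p 0.0125), from 5.97 to 3.32 for rps (0.00940), from 4.22 to 2.56 for lin (0.00940) and from 3.41 to 3.72 for vps (0.0376). It went from 3.61 to 3.34 for hsp (0.0564), from 3.19 to 3.16 for dnj (0.0806), from 4.63 to 3.22 for vha (0.0877) and from 3.70 to 3.0002 for eif (0.0877), which did not pass. It fell further for unc, from 2.81 to 1.21 (0.833), for egl, which here includes the tagged gene, from 3.43 to 1.54 (0.833), and for pqn, from 2.5965 to 1.47 (0.791). It was 0 matched and unmatched for str (0.0752) and srw (0.232), and went from 0.233 to 0.3398 for fbxa (0.232).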
